A study of Homo sapiens with 4 samples.

How the data were processed

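Total poly(A) RNA (input) and polyribosome-bound RNA of KYSE-150 cells were measured by RNA sequencing in control cells and in cells with a stable hairpin against NSUN6. There were 4 libraries, 1 per group. Groups were taken from the sample titles and columns from the header names, which match the sample descriptions.

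The authors deposited 1 table with FPKM per gene symbol for the 4 libraries, that is fragments normalized to transcript length and to all mapped fragments. The submitters' processing notes name TopHat, with no version, and the genome builds hg19 and GRCh37. The counting tool, its strand setting, the annotation and any filters are not given in the sources used here. Libraries were made with a stranded mRNA kit, per the labels' protocols. The authors also deposited a translation efficiency ratio per gene for control and for knockdown cells. Per the labels it is polyribosome FPKM over input FPKM, and the values show that 5 was added to both FPKM (largest gap to the deposited ratio 5e-10).

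The last line of the table is a second line of column names. In the order of the columns it gives a K150 input and a K150 polyribosome library with a hairpin against GFP, and then a K30 input and a K30 polyribosome library with a hairpin against Mettl1. The header calls the last 2 columns the knockdown polyribosome library and the knockdown input, in that order. The header was followed, and the other order was run as an alternative. The table has 17064 rows of values. In 26 rows a number of 5 digits stands in place of a gene name and 2 rows have no name. These 28 rows entered the counts and named no gene.

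The depth of the libraries is unknown. The lowest value above 0 is 0.01 FPKM in each library, the rounding limit of the table, so whole reads could not be recovered and no interval or floor was computed. The FPKM of a library summed to 579251 in control input, 564769 in control polyribosome RNA, 538002 in knockdown input and 627887 in knockdown polyribosome RNA. The 10 highest genes took 9.51%, 7.84%, 6.51% and 10.8% of these sums.

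Changes were computed as differences of log2(FPKM + 1), which understates the change of low genes. Translation efficiency was the log2 of (polyribosome FPKM + 1) over (input FPKM + 1), and its change was knockdown-labelled minus control. Genes with a mean of at least 5 FPKM over the 4 libraries were kept, 7379 in all. With 1 library per group there was no test, so genes at least 2-fold higher or lower were counted.

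The following choices were made before the data were examined. The genes named are NSUN6 and, for the change in efficiency, input and polyribosome RNA, the 10 highest and 10 lowest genes with a mean of at least 10 FPKM, a symbol and a single row. For efficiency the mean of the 2 inputs also had to be at least 5 FPKM. For each list described, its 2 highest and 2 lowest members could be named. Outside this rule, COPB1 and CD68 (from counts of 5 or fewer genes), the genes at the ends of 2 chromosome runs and the cancer/testis genes described apart were named after their values were seen. The 28 gene lists cover ribosomal proteins, translation factors, aminoacyl-tRNA synthetases, 5-methylcytosine proteins, mitosis, DNA replication, oxidative phosphorylation, mitochondrially encoded mRNAs, long non-coding RNAs, histones, the integrated stress response, endoplasmic reticulum chaperones, cytosolic chaperones, p53 targets, squamous epithelium, epithelial-mesenchymal transition, interferon response, NF-kB, cholesterol synthesis, glycolysis and hypoxia, growth factor signalling, immediate early genes, the proteasome, ribosome biogenesis, the spliceosome, extracellular matrix, selenoproteins and markers of other cell types. A list with at least 5 members past the filter was described by its median and the percentile of that median among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. Percentiles under 2.5 or over 97.5 were called past the limits. This describes these libraries and is not a test between conditions. In this way 25 lists could be described. Of the mitochondrially encoded mRNAs 0 of 13 were in the table, of the long non-coding RNAs 1 of 34 was in the table and 0 passed the filter, and of the markers of other cell types 1 passed the filter.

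GC content and length were taken from 1 transcript per gene in GENCODE 29, matched by symbol or an unambiguous older symbol for 7337 of the 7379 genes (99.4%). A quadratic trend on GC content and log2 length was fitted across genes and removed, and the mean was kept. The order of genes on chromosomes was taken from a RefSeq table of GRCh38.p14. No coordinates are given, because that is not the build named in the processing notes. Genes with near-identical copies or overlapping neighbours, such as the MTRNR2L genes, UBB, HSPA1A and HSPA1B, LUZP6 and HOTS, are uncertain. Values of some genes are not reported here.

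The alternatives were a pseudocount of 0.1, a filter at a mean of 1 FPKM or none, libraries rescaled to a sum of 1000000, changes centred on the median, the authors' deposited ratio, the knockdown-labelled fractions exchanged, and GC content and length removed. The last 2, and other thresholds for genes high in 1 pair of libraries, were added after the data were seen. Rescaling moved the median input change of all genes from 0.01 to 0.11 and the median polyribosome change from -0.28 to -0.43. List percentiles are relative to other genes of the same libraries.

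The calculations were tested on simulated data. For the counts and lists, each simulated library was the control input with independent noise of an SD of 0.2 on the log2 scale. The SD between the 2 real inputs was 1.29. These counts thus check the calculation and give no error rate for these libraries. For the input change over 7608 genes, 100% of genes raised 4-fold and 100% of genes lowered 4-fold were counted as at least 2-fold different, and 3 unchanged genes were. Of random unchanged lists 6.5% passed the limits, and of lists shifted by 0.3 on the log2 scale 96% did. For the efficiency change over 7550 genes, a planted GC trend with 50% of the variance was found at 49.2%. For the input change over 7550 genes, 0 of 20 random gene orders passed the neighbour test, and planted regional shifts with an SD of 0.5 gave a correlation of 0.34. The motif test on 7550 simulated genes put genes lowered by 0.2 at the 0th percentile and genes not lowered at the 64.0th. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.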

Results

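RNA was sequenced from KYSE-150, an established line of esophageal squamous cell carcinoma, with and without a stable short hairpin RNA against NSUN6. NSUN6 is an RNA methyltransferase that forms 5-methylcytosine. Cells were treated with cycloheximide, which stops elongating ribosomes on their mRNAs. Part of each lysate was kept as input, and the rest was spun through a sucrose cushion to collect RNA bound to polyribosomes. The 4 libraries are control input, control polyribosome, knockdown input and knockdown polyribosome, with 1 library per group. No difference below therefore has a replicate check, and no p-value was computed. Values are FPKM, and the read depth of the libraries is unknown. The number of genes above 0 FPKM was 14645 in control input, 14685 in control polyribosome RNA, 15081 in knockdown input and 14713 in knockdown polyribosome RNA. A second line of column names at the end of the deposited table names the control columns as K150 and the knockdown columns as K30 with a hairpin against Mettl1. It also gives the 2 knockdown fractions in the opposite order to the header. The header matches the sample labels and was used, so the second pair is called knockdown-labelled throughout.

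NSUN6 itself was lower in both knockdown-labelled libraries. In input RNA it was at 8.85 FPKM in control and 3.83 FPKM in knockdown-labelled cells, or 43.3% of control. In polyribosome RNA it was at 10.13 FPKM in control and 0.38 FPKM in knockdown-labelled cells, or 3.75% of control. The input difference of -1.03 on the log2(FPKM + 1) scale stood at the 13.9th percentile of the 7379 genes with a mean of at least 5 FPKM, so many other genes differed by more. The log2 translation efficiency of NSUN6 was 0.18 in control and -1.81 in knockdown-labelled cells, a difference of -1.98. With the knockdown-labelled fractions exchanged, NSUN6 was at 4.29% of control in input and 37.8% in polyribosome RNA, and the efficiency difference was 1.63. With GC content and length removed that difference was -0.56 and the polyribosome difference -1.75. In the authors' deposited table its efficiency, computed with another added constant, was 1.09 and 0.609.

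The first comparison asked which mRNAs were more or less abundant on polyribosomes than in input RNA of control cells. Translation efficiency here is the log2 ratio of polyribosome to input FPKM with 1 added to each. Messages for the proteasome, which degrades ubiquitinated proteins, were enriched on control polyribosomes, with a list median of 0.42 over 31 genes. PSMA3 had the highest value among them, 0.77, and PSMD12 the lowest, 0.12. Cytosolic chaperones (median 0.40 over 23 genes) and nuclear-encoded oxidative phosphorylation genes (0.37 over 45 genes) were likewise high. Among them were CCT5 of the cytosolic chaperonin at 0.57 and COX7B of respiratory complex IV at 0.60. Each of these 3 medians lay above those of all 10000 expression-matched random lists. DNA replication genes (0.31), aminoacyl-tRNA synthetases (0.26), ribosome biogenesis genes (0.22), spliceosome genes (0.22), endoplasmic reticulum chaperones (0.21) and glycolysis genes (0.20) also passed the upper limit set on random lists. Messages for cytosolic ribosomal proteins were low on control polyribosomes, with a median of -0.29 over 79 genes, below all random lists. RPLP1 was at -1.36 and RPS27 at -1.23, whereas RPL22 was at 0.18. Immediate early genes, which are transcribed within minutes of stimulation, had a median of -0.18 over 20 genes, with EGR1 at -0.55 and FOSB at -0.46. Growth factor and oncogene messages had a median of -0.12 over 28 genes, and NFE2L2, the oxidative stress regulator, was at -1.36. In all, 0 of 7379 genes were at least 2-fold higher on control polyribosomes and 56 were at least 2-fold lower. The glycolysis list moved to the 97.0th percentile and the growth factor list to the 3.15th when GC content and transcript length were removed. The endoplasmic reticulum list, at 0.21, no longer passed the limit with a pseudocount of 0.1.

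The second comparison asked how input RNA differed between knockdown-labelled and control cells. KRT5, a keratin of basal squamous epithelium, was at 906 FPKM in control input and 0.45 FPKM in knockdown-labelled input, a log2 difference of -9.29. KRT19, a keratin of simple epithelium, was at 0.07 FPKM in control and 1488 FPKM in knockdown-labelled input, a difference of 10.44. UBB, a polyubiquitin gene, was at 0.58 FPKM in control and 3124 FPKM in knockdown-labelled input. AGR2, a disulfide isomerase of secretory cells, was at 0.25 and 1093 FPKM. MGST1, a membrane glutathione transferase, and SPRR3, a cornified envelope protein, were listed at 0 in control input and at 444 and 413 FPKM in knockdown-labelled input. MSN, which encodes the cytoskeletal linker moesin, differed by -7.15, TGM2, a transglutaminase, by -6.77, and AKR1B1, the aldose reductase, by -6.42. CTAG2 and CSAG1, both of cancer/testis antigen families, differed in opposite directions, by 7.92 and -6.51. CHCHD10, a mitochondrial protein gene, was higher by 7.60.

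**Figure D1:**
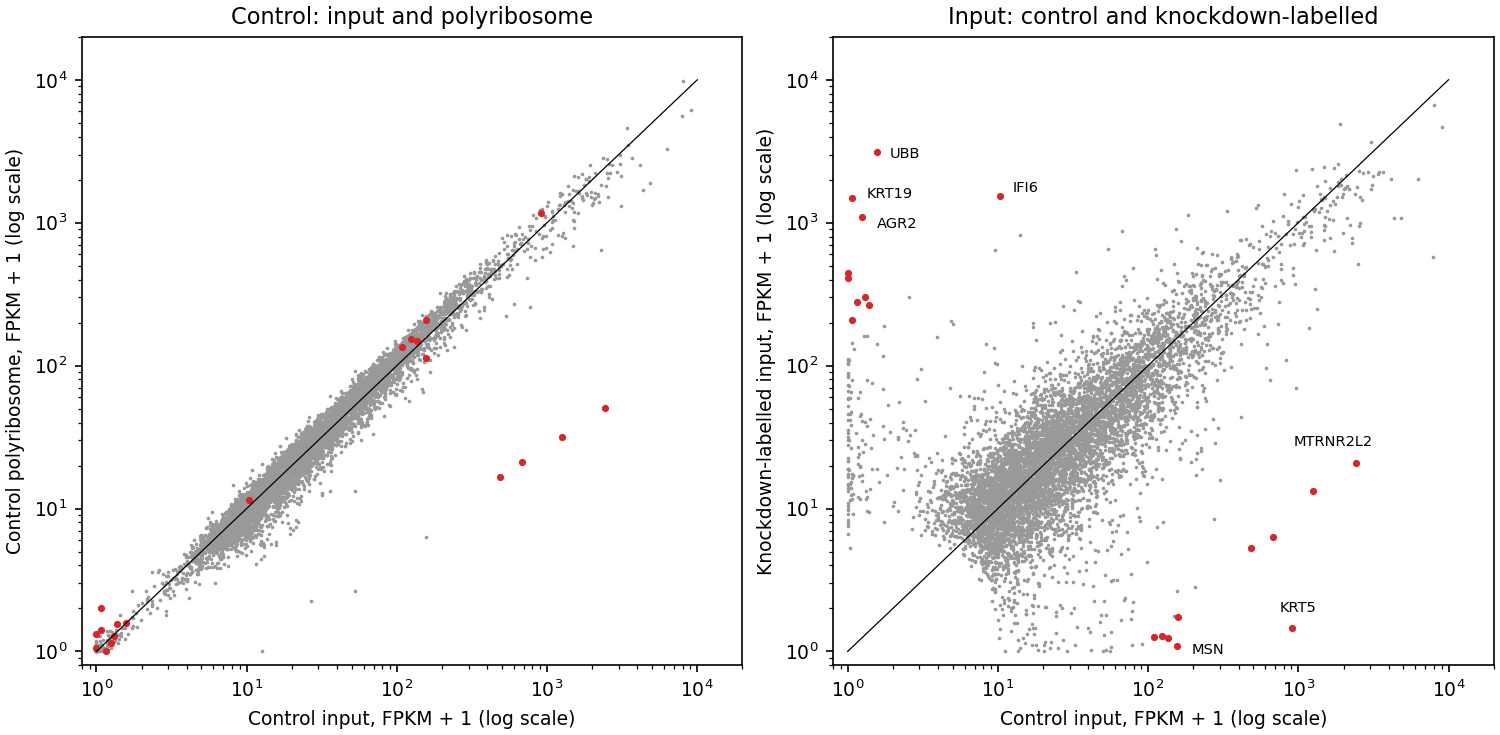
FPKM + 1 of each gene with a mean of at least 5 FPKM, on log axes. The left panel sets the control polyribosome library against control input and the right panel sets knockdown-labelled input against control input, with genes named for the input difference in red and the line of equal values in black. The left cloud is narrow (log2 differences with an SD of 0.33 across genes) and the right cloud is wide (SD of 1.29), with KRT5 and UBB far from the line.

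Interferon-induced genes were higher in knockdown-labelled input as a group. Of 25 members, 16 were at least 2-fold higher and 1 was at least 2-fold lower, and the median of 1.61 lay above all random lists. IFI27 was at 0.30 and 303 FPKM, BST2, which tethers budding virions, at 0.38 and 263 FPKM, and IFI6 at 9.35 and 1541 FPKM. IFITM2, by contrast, was at 42.1 and 1.89 FPKM. Inflammatory genes of the NF-kB list were lower, with 10 of 12 at least 2-fold lower and a median of -1.71. The cytokine IL1B was at 123 and 0.29 FPKM and the adhesion molecule ICAM1 at 55.4 and 0.07 FPKM, while the inhibitor NFKBIA differed by 0.25. Integrated stress response genes were also lower, with 13 of 26 at least 2-fold lower and a median below those of all random lists. They included CTH of cysteine synthesis at -3.36 and DDIT4, an inhibitor of mTORC1 signalling, at -2.66, whereas the transcription factor ATF5 was at 3.46. Ribosomal protein genes had a median of -0.32, with 11 of 79 at least 2-fold lower. Medians passed the upper limit for spliceosome genes (0.70, with SRSF1 at 2.14), endoplasmic reticulum chaperones (0.64, with DNAJB11 at 2.26), cytosolic chaperones (0.62) and DNA replication genes (0.60, with CCNE1 at 2.57). HSPA1A and HSPA1B, the stress-inducible HSP70 genes, were at 3.77 and 2.43, and since their sequences are nearly identical the split between them is uncertain. Cholesterol synthesis genes had a median of 0.55, and DHCR7, the last enzyme of the pathway, was at 0.07 and 142 FPKM. That list moved to the 96.5th percentile after removal of GC content and length. Ribosomal proteins were then at -0.18, and translation factors (-0.26), aminoacyl-tRNA synthetases (-0.49) and glycolysis genes (-0.39) came to pass the lower limit. Squamous epithelium and keratinization genes went both ways, with 11 of 34 at least 2-fold higher and 11 at least 2-fold lower, and their median of 0.28 was within the limits of random lists. The second line of column names gives the knockdown-labelled fractions in the other order. With them exchanged, 5 of the 9 input lists past the limits crossed the middle of random lists but ended within the limits. Their medians were -0.10 for spliceosome genes, -0.45 for endoplasmic reticulum chaperones, -0.24 for cytosolic chaperones, -0.30 for DNA replication genes and 0.19 for ribosomal proteins. The cholesterol list moved to the 96.0th percentile, interferon-induced genes fell to 0.70, SRSF1 to 0.24 and DNAJB11 to 0.79, while CTH was at -4.04 and ATF5 at 4.16. The number of genes at least 2-fold lower was then 2343.

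In all, 973 of 7379 genes were at least 2-fold higher and 1065 at least 2-fold lower in knockdown-labelled input. By a threshold chosen after the values were seen, 49 genes were at 20 FPKM or more in both knockdown-labelled libraries and under 1 FPKM in both control libraries, and 27 genes were the reverse. Between the 2 fractions of the same cells, 0 genes met this threshold in control and 3 did in knockdown-labelled cells, namely LUZP6, HAT1 and COPB1, the last named after its values were seen. This contrast depends on the threshold. With 10 FPKM in place of 20 the counts between cells were 85 and 44, and those between fractions were 1 in control and 81 in knockdown-labelled cells. Across genes, which are not independent replicates, Pearson's r of log2(FPKM + 1) was 0.983 between the control fractions, 0.829 between the knockdown-labelled fractions and 0.730 between the 2 inputs. Of the fixed markers of fibroblasts, endothelium and immune cells, 22 were in the table and 1 passed the filter. That gene, CD68, also named after its values were seen, was at 71.2 FPKM in control input and 5.90 FPKM in knockdown-labelled input.

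The third comparison asked how polyribosome RNA differed between knockdown-labelled and control cells. Many of the genes furthest apart were those of the input comparison, and 12 genes were named for both. KRT5 differed by -9.42, MSN by -7.67, IL1B by -7.23, AKR1B1 by -6.66 and TGM2 by -6.49. UBB differed by 10.79, KRT19 by 9.93, IFI27 by 8.38, AGR2 by 8.11, CHCHD10 by 7.96 and BST2 by 7.76. CYBA, a subunit of the phagocyte NADPH oxidase, was lower by a log2 difference of -6.61, SAA1, an acute phase protein, by -6.36, CCND2, a cyclin of G1 phase, by -6.20, and ANXA3, an annexin, by -5.94. IGFBP2, which binds insulin-like growth factors, was at 0.24 FPKM in control and 245 FPKM in knockdown-labelled polyribosome RNA. CTAG2 was listed at 0 in control polyribosome RNA and at 537 FPKM in the knockdown-labelled library. GAL, the galanin precursor, was listed at 0 in both control libraries and at 186 FPKM in knockdown-labelled polyribosome RNA. MAGEA12, a cancer/testis antigen gene, was at 61.2 FPKM in control polyribosome RNA and listed at 0 in both knockdown-labelled libraries. HOTS, at 2.44 and 839 FPKM, overlaps the H19 transcript and is uncertain.

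Several lists were lower in knockdown-labelled polyribosome RNA, whereas ribosomal protein genes were higher. Aminoacyl-tRNA synthetases had a median of -2.29, with 15 of 20 at least 2-fold lower, among them EPRS at -3.69 and GARS at -3.61. Mitotic genes had a median of -1.77, with 18 of 26 at least 2-fold lower, including the spindle protein NUSAP1 at -3.77 and the cytokinesis protein ANLN at -3.10. Translation factors had a median of -1.38 and 24 of 40 at least 2-fold lower, with EIF3M at -3.78 and EIF4G2 at -3.38. Ribosome biogenesis genes had a median of -1.31, with the helicase DDX21 at -3.83. NF-kB genes (-1.92), integrated stress response genes (-0.99), glycolysis and hypoxia genes (-0.98), cytosolic chaperones (-0.76) and proteasome genes (-0.82) were also below the lower limit. CA9, a hypoxia-induced carbonic anhydrase, was at -4.91 and the glucose transporter SLC2A3 at -4.29, while the lactate transporter SLC16A3 was at 2.41. Epithelial-mesenchymal transition genes had a median of -1.01, with CD44 at -3.99 but TGFBI at 4.58. The proteasome list moved to the 12.8th percentile and the epithelial-mesenchymal list to the 9.22nd after removal of GC content and length, and the second was also lost at a mean of at least 1 FPKM, where its median was -0.97. Interferon-induced genes had a median of 0.58, with 11 of 25 at least 2-fold higher, and ribosomal protein genes had a median of 0.50, with 17 of 79 at least 2-fold higher. In all, 1230 genes were at least 2-fold higher and 2426 at least 2-fold lower, so 33.6% of these genes were higher. With changes centred on the median of all genes, which was -0.28, the share was 45.8%. With GC content and length removed, 761 were higher and 1915 lower, a share of 28.4%. The median of all genes was then -0.37, and this share was not centred on it. With the knockdown-labelled fractions exchanged, 936 genes were at least 2-fold higher and 1031 lower, a share of 47.6%. Most of the lists above then lost their call or shrank. The medians of translation factors (-0.26), mitotic genes (-0.18), ribosome biogenesis genes (-0.17), proteasome genes (-0.23) and ribosomal proteins (-0.03) were no longer past the limits. Aminoacyl-tRNA synthetases (-0.68) and glycolysis genes (-0.62) stayed past them at smaller sizes, and interferon-induced genes (1.53) at a larger one. Among named members, EPRS was at -1.19, GARS at -1.13, NUSAP1 at -0.31, ANLN at -0.68, EIF3M at -1.22, EIF4G2 at 0.38, DDX21 at -0.62, CD44 at -1.98 and SLC16A3 at 1.76. In addition, 2 of the 12 lists past the limits crossed the middle of random lists. Cytosolic chaperones, at 0.69, were then past the upper limit, and epithelial-mesenchymal transition genes, at 0.10, were within the limits. With GC content and length removed, the median was -0.80 for translation factors, with 13 of 40 at least 2-fold lower, and -1.10 for mitotic genes, with 14 of 26. It was 0.30 for ribosomal proteins, and further from 0 for interferon-induced genes (1.15) and integrated stress response genes (-1.52). Cholesterol synthesis genes came to pass the upper limit, at 0.27. Among named members, the removal moved EIF3M to -2.08, EIF4G2 to -2.36, ANLN to -1.67, DDX21 to -2.42, EPRS to -2.65 and SLC16A3 to 1.48. CA9, by contrast, moved further from 0, to -5.78.

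The fourth comparison, for which the series was designed, set translation efficiency in knockdown-labelled cells against that in control cells. Among genes with a mean of at least 10 FPKM, the lowest log2 difference in the header's column order was -4.65, for HSP90AA1, a cytosolic chaperone. With the fractions exchanged, HSP90AA1 was at 4.44. Its FPKM was 160 in input and 172 on polyribosomes in control, and 232 in input and 8.97 on polyribosomes in knockdown-labelled cells. ANXA1, a phospholipid-binding annexin, differed by -4.58, TARS, the threonyl-tRNA synthetase, by -4.31, and METAP2, which removes initiator methionine, by -4.10. CAPZA1, which caps actin filaments, differed by -4.03, the histone acetyltransferase HAT1 by -3.94, the scaffold protein SDCBP by -3.93, the proteasome ATPase PSMC6 by -3.89 and the mitochondrial chaperonin HSPD1 by -3.88. LUZP6, at -4.44, overlaps MTPN and is uncertain. In the other direction, FTL, the ferritin light chain, differed by 5.16, with 2285 FPKM in input and 640 on polyribosomes in control against 775 and 7781 in knockdown-labelled cells. The lysosomal sulfatase IDS differed by 4.23, the ribosomal stalk protein RPLP1 by 3.93 and SEPW1, a selenoprotein, by 3.86. With the header's column order, the highest values among these genes belonged to 6 MTRNR2L genes, from 6.30 for MTRNR2L6 to 8.36 for MTRNR2L1. With the fractions exchanged they were at 1.38 to 3.13, below LUZP6 at 5.05. These are nuclear copies related to mitochondrial 16S ribosomal RNA, and their values are uncertain because reads can be shared among near-identical copies. MTRNR2L2 was at 2427 FPKM in control input and 49.1 FPKM in control polyribosome RNA, and at 19.8 and 114 FPKM in the knockdown-labelled pair. In the authors' deposited table the knockdown over control ratio of efficiency was 0.0550 for HSP90AA1, 0.0539 for ANXA1 and 35.4 for FTL.

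**Figure D2:**
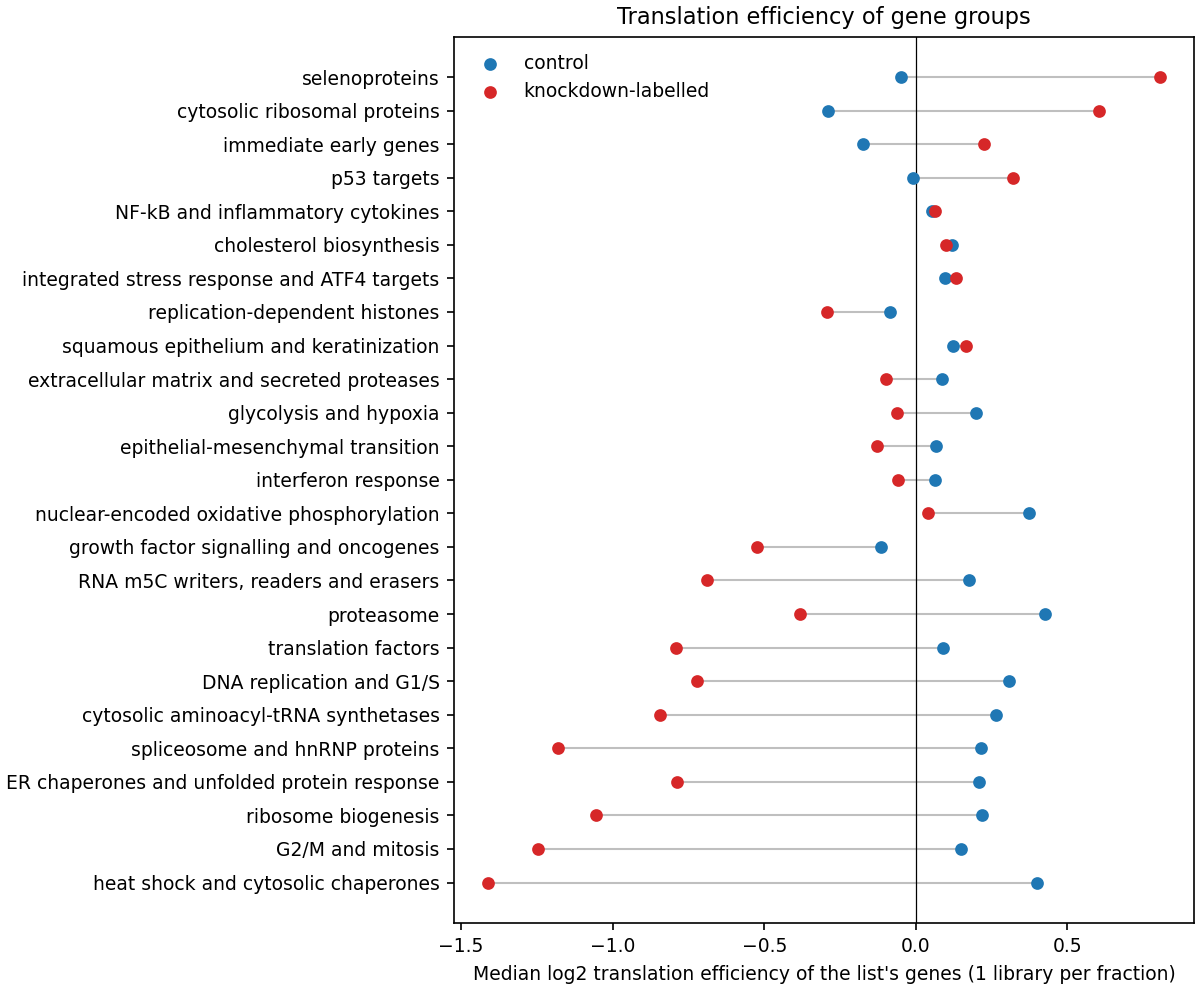
Median log2 translation efficiency of 25 gene lists in control (blue) and knockdown-labelled cells (red), 1 library per fraction, sorted by the median difference per gene. Cytosolic chaperones lie at 0.40 in control and -1.41 in knockdown-labelled cells, and ribosomal proteins lie at -0.29 and 0.60.

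With the header's column order, cytosolic chaperones had the lowest list median of the efficiency difference, -1.85, with 14 of 23 genes at least 2-fold lower and 0 higher. With the fractions exchanged their median was 1.01, below the 1.07 of mitotic genes. The other values of this paragraph are in the header's order. Mitotic genes had a median of -1.43, with 17 of 26 at least 2-fold lower, among them the cyclin-dependent kinase CDK1 at -3.40. Ribosome biogenesis genes had a median of -1.26 and 21 of 34 at least 2-fold lower, including the nucleolar proteins NPM1 at -3.85 and NCL at -3.53. Spliceosome genes (-1.23, with 24 of 36 at least 2-fold lower), endoplasmic reticulum chaperones (-1.23, 11 of 20) and aminoacyl-tRNA synthetases (-1.21, 10 of 20) followed. HNRNPA2B1 was at -3.25, CANX, a lectin chaperone, at -3.29 and NARS at -3.41. DNA replication genes had a median of -0.90 with RFC3 of the clamp loader at -3.08, although the transcription factor E2F1 was at 1.92. Translation factors had a median of -0.90, with 20 of 40 at least 2-fold lower, and proteasome genes one of -0.78, with 15 of 31. EIF3E was at -3.31 and PSMA3 at -3.35, while TPT1 was at 1.59. Oxidative phosphorylation genes had a median of -0.28, with 12 of 45 at least 2-fold lower. Past the upper limit were ribosomal proteins, with a median of 0.85 and 34 of 79 at least 2-fold higher, and selenoproteins, with a median of 0.96 and 7 of 14 at least 2-fold higher. RPS29 was at 3.26 and the glutathione peroxidase GPX4 at 2.42, whereas RPL7 was at -1.56 and the thioredoxin reductase TXNRD1 at -2.60. Genes that write, read or erase 5-methylcytosine in RNA had a median of -0.68 over 9 members, at the 15.9th percentile of random lists. The medians of p53 targets (0.27), replication-dependent histones (-0.11) and extracellular matrix genes (-0.18) were also within the limits.

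In all, 885 of 7379 genes had an efficiency at least 2-fold higher and 2221 at least 2-fold lower in knockdown-labelled cells, so 28.5% of these genes were higher. With each library rescaled to the same FPKM sum, 584 were higher and 2624 lower, a share of 18.2%, and the median of all genes moved from -0.12 to -0.37. The SD of log2 translation efficiency across genes was 0.33 in control and 1.22 in knockdown-labelled cells. Efficiency followed the GC content of the transcript in knockdown-labelled cells, with Spearman's rho of 0.82 across genes, against 0.02 in control cells. With genes split by GC content into 5 groups of equal size, the group with the lowest, 31.8 to 43.9%, had a median efficiency difference of -1.87, and the group with the highest, 60.3 to 74.7%, had one of 0.74. With GC content and length removed, 396 genes were at least 2-fold higher and 1307 at least 2-fold lower. Of the 12 lists past the limits, 11 stayed past them on the same side, and oxidative phosphorylation genes moved to the 22.9th percentile. Interferon-induced genes (-0.90), squamous epithelium genes (-0.80) and glycolysis genes (-0.77) came to pass the lower limit, so 14 lists were past the limits. Medians of the 11 were nearer 0 for all but the proteasome (-0.92), with -0.74 for mitotic genes (7 of 26 at least 2-fold lower), -0.79 for spliceosome genes (16 of 36), -1.22 for cytosolic chaperones, 0.55 for ribosomal proteins and 0.41 for selenoproteins (3 of 14 at least 2-fold higher). Translation factors were at -0.77, with 12 of 40 at least 2-fold lower. The median of all genes was then -0.39, so distance from 0 is not distance from other genes. Ribosomal proteins were at 0.85 against a middle of random lists of 0.14 before the removal, and 0.55 against -0.47 after it. Translation factors were at -0.90 against 0.07 before it, and -0.77 against -0.44 after it. With the knockdown-labelled fractions exchanged, as in the second line of column names, 2049 genes were at least 2-fold higher and 464 at least 2-fold lower, and 11 of the 12 lists and 15 of the 21 named genes, NSUN6 included, had the opposite sign. The list that kept its sign, oxidative phosphorylation, was at -0.35. Of the 15 list members named above, 14 had the opposite sign, and TPT1 was at 0.95. With GC content and length removed all 15 kept their sign but moved by more than 1.5-fold, from -3.40 to -1.49 for CDK1 and from 2.42 to 1.00 for GPX4. The direction of the fourth comparison, and in part that of the input and polyribosome comparisons, thus depends on which knockdown-labelled column is which.

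**Figure D3:**
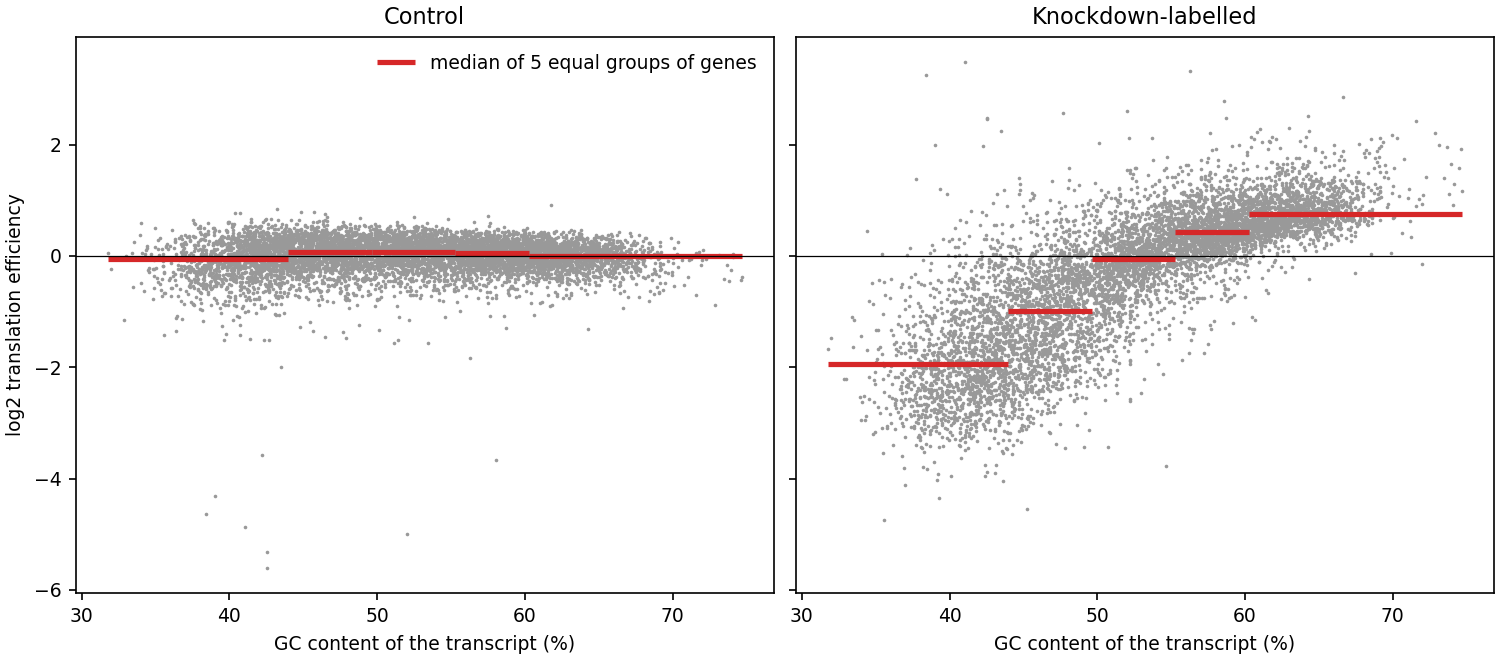
Log2 translation efficiency of each gene against the GC content of its transcript in percent, in control (left) and knockdown-labelled cells (right). Red bars are medians of 5 equal groups of genes by GC content. In control they lie between -0.06 and 0.08, and in knockdown-labelled cells they go from -1.95 in the lowest group to 0.75 in the highest.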

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

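The tests of exchanged columns and of GC content in the polyribosome change were chosen after the results were seen. So were the threshold for genes high in 1 pair of libraries and the search for runs of genes. The same holds for the cancer/testis genes and the chromosome medians. The other tests below were written before their own result was seen, but those of the first and second pattern address patterns already seen. The results listed first are those whose translation efficiency was above 1 (log2 above 0) in one pair of libraries and below 1 in the other, by a log2 value of at least 0.25 in each for lists and at least 1 in each for genes. With 1 library per group, none of these differences was tested. Ribosomal proteins had a median log2 efficiency of -0.29 in control and 0.60 in knockdown-labelled cells, a difference of medians of 0.89. The opposite was seen for cytosolic chaperones (0.40 and -1.41, difference -1.81), aminoacyl-tRNA synthetases (0.26 and -0.84, difference -1.11), DNA replication genes (0.31 and -0.72, difference -1.03) and proteasome genes (0.42 and -0.38, difference -0.81). With the knockdown-labelled fractions exchanged, the second values become -0.60, 1.41, 0.84, 0.72 and 0.38, on the same side as control, so none of these lists would be flagged. Among single genes the difference was 8.36 for MTRNR2L1, 8.06 for MTRNR2L2, 7.89 for MTRNR2L10, 7.80 for MTRNR2L8, 7.60 for MTRNR2L9 and 6.30 for MTRNR2L6, but 1.39, 3.13, 1.38, 2.83, 2.40 and 2.31 in the same order with the knockdown-labelled fractions exchanged. It was 5.16 for FTL, 4.23 for IDS, 3.93 for RPLP1 and 3.86 for SEPW1, but -1.49, -0.24, -1.21 and -1.71 with the fractions exchanged.

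The first pattern is the size of the differences between the control and the knockdown-labelled libraries in both fractions, with 49 genes at 20 FPKM or more in both knockdown-labelled libraries and under 1 FPKM in both controls, and 27 the other way (85 and 44 at 10 FPKM). GC content and transcript length explained 0.983% of the variance of the input change across genes. In the header's column order this argues against such a bias as the cause of the input differences. They explained 29.9% of the variance of the polyribosome change (rho of 0.62 with GC content), where such a bias may account for part. These shares were not computed with the knockdown-labelled fractions exchanged, so for that order a bias in input stays open. If the knockdown-labelled libraries came from another cell line, as the second line of column names says, genes in regions of different copy number would shift together, and the input change, with GC content and length removed, correlated with the mean of genes 5 to 25 places away on the same chromosome with r of 0.297, whereas 1000 shuffles of the gene order gave -0.058 to 0.052. A run of 21 genes on chromosome 17 from UBB to SHMT1 had a median of 1.41 with 20 genes above 0, and a run on chromosome 1 from NEK2 to AIDA had one of -1.54, where 100 shuffles gave -1.21 to 1.06. Shuffling also separates neighbours that are regulated together, so these ranges cannot tell copy number from shared regulation. These values thus leave another line as a candidate explanation. Copy number differences between clones of one line and an effect of the hairpin itself, against NSUN6 or Mettl1, also stay open, as they were not tested.

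The second pattern is the wide spread of translation efficiency in the knockdown-labelled cells (SD of 1.22 against 0.33 in control). GC content and length explained 66.6% of its variance and the SD left was 0.70, so a bias between these 2 libraries may account for most of it, but the fitted trend left more spread than the control pair had. Exchanged columns would put genes low on control polyribosomes high in the knockdown-labelled efficiency, as all 6 MTRNR2L genes were. By contrast, the 50 others at least 2-fold lower on control polyribosomes had a median of -0.85 (2.06th percentile). With GC content and length removed, 48 of them had a median of 0.40 (100th percentile). The mean of all genes was -0.35 before the removal and 0 after it, so percentiles can be compared across it but signs cannot. The 50 genes with the highest control efficiency had a median of -1.21 (0th percentile, 30 at least 2-fold lower), or -0.32 after the removal (0th percentile), as exchanged columns would give. Across genes, control and knockdown-labelled log2 efficiency had Spearman's rho of -0.12, or -0.19 after the removal, also the sign that an exchange would give. The -0.85 before the removal goes the other way, so these values leave the order of the columns open. The authors' deposited ratio follows the header's order but was computed from the same columns. An effect of the hairpin on translation also stays open, untested without replicates. The labels give its target as NSUN6 and the second line of column names gives it as Mettl1.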

How the results depend on the processing

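The exchange of the knockdown-labelled fractions, other thresholds for genes high in 1 pair of libraries and the removal of GC content and length were chosen after seeing the data. No paired analysis was possible because each group has 1 library, and for the same reason no library could be left out. Depth is unknown, so low values have no stated precision. With a pseudocount of 0.1, changes centred on the median, and the authors' deposited ratio, each count of genes at least 2-fold higher or lower stayed within 1.5 times its value. Over the 8 alternatives, 31 counts stayed within that range and 13 did not. Of the list medians, 683 stayed on the same side of the limits, 24 came to pass them, 14 no longer did and 29 reversed. Reversed means that the median crossed the middle of random lists, in some cases ending within the limits. Of the named genes' values, 315 stayed within 1.5-fold, 131 kept their sign but moved by more (41 with a pseudocount of 0.1, 34 with GC content and length removed, 25 under the exchange, 19 rescaled and 12 in the deposited ratio) and 15 changed sign. Of the values of list members named in the report, 293 stayed within 1.5-fold, 50 kept their sign but moved by more (25 with GC content and length removed and 13 under the exchange) and 15 changed sign. All reversals were under the exchange. Counts of genes at 20 FPKM or more in 1 pair of libraries and under 1 FPKM in the other were 49 and 27, against 85 and 44 at 10 FPKM and 27 and 13 at 50 FPKM. Between the knockdown-labelled fractions 3 genes met the threshold, 81 at 10 FPKM and 0 at 50 FPKM.

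At a mean of at least 1 FPKM, 3755 genes were at least 2-fold lower in polyribosome RNA, and more genes were counted there. With no filter, 3344 genes were lower in efficiency, 1615 higher and 1679 lower in input and 3818 lower in polyribosome RNA, again from more genes. Rescaled libraries gave 584 genes higher in efficiency, since the median shifted by the scaling. With GC content and length removed, 396 genes were higher and 1307 lower in efficiency and 761 higher in polyribosome RNA; the cause was not tested beyond the trend removed.

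With the fractions exchanged, 2049 genes were higher and 464 lower in efficiency, 2343 were lower in input and 1031 lower in polyribosome RNA. The reversed medians of the efficiency change were 0.92 for translation factors, 0.48 for aminoacyl-tRNA synthetases, 1.07 for mitosis, 0.46 for DNA replication, 0.45 for endoplasmic reticulum chaperones, 1.01 for cytosolic chaperones, 0.21 for the proteasome, 0.79 for ribosome biogenesis, 0.89 for the spliceosome and -0.64 for selenoproteins. Oxidative phosphorylation stayed negative, at -0.35, and moved from the 0.41st percentile of random lists to the 75.1st, within the limits. Selenoproteins, at the 3.26th percentile, were also within the limits. Ribosomal proteins went to -0.15 without leaving the upper side of random lists. Single genes reversed to 1.63 (NSUN6), 4.44 (HSP90AA1), 4.13 (ANXA1), 5.05 (LUZP6), 3.76 (TARS), 3.82 (METAP2), 3.89 (CAPZA1), 4.30 (HAT1), 3.90 (SDCBP), 3.28 (PSMC6), 3.24 (HSPD1), -1.49 (FTL), -0.24 (IDS), -1.21 (RPLP1) and -1.71 (SEPW1). List members reversed to 3.12 (CDK1), 2.87 (NPM1), 3.22 (NCL), 2.47 (HNRNPA2B1), 3.17 (CANX), 3.36 (NARS), 3.01 (RFC3), -1.19 (E2F1), 4.28 (EIF3E), 1.80 (PSMA3), -0.97 (RPS29), -1.67 (GPX4), 1.21 (RPL7) and 2.15 (TXNRD1) in efficiency and to 0.38 (EIF4G2) in polyribosome RNA. In input the medians were 0.19 for ribosomal proteins, -0.30 for DNA replication, -0.45 for endoplasmic reticulum chaperones, -0.24 for cytosolic chaperones and -0.10 for the spliceosome, all within the limits. In polyribosome RNA they were 0.69 for cytosolic chaperones, past the upper limit, and 0.10 for epithelial-mesenchymal transition, within the limits. The knockdown-labelled efficiency took the opposite sign by construction, with -0.60 for ribosomal proteins, 0.79 for translation factors, 0.84 for aminoacyl-tRNA synthetases, 1.25 for mitosis, 0.72 for DNA replication, 0.79 for endoplasmic reticulum chaperones, 1.41 for cytosolic chaperones, 0.38 for the proteasome, 1.06 for ribosome biogenesis, 1.18 for the spliceosome and -0.81 for selenoproteins. These reversals follow from which column is taken as which fraction.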

Other observations

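Cancer/testis antigen genes, a family chosen after the data were seen by the start of their symbols, differed in makeup between the cells. Of 36 in the table, 12 reached 5 FPKM in at least 1 library. In knockdown-labelled input 3 of these were at least 2-fold higher and 6 at least 2-fold lower. In polyribosome RNA, and in input with the knockdown-labelled fractions exchanged, 3 were higher and 3 lower. MAGEB2 was at 0.73 FPKM in control and 67.8 FPKM in knockdown-labelled input, and MAGEA10 at 0.17 and 25.8 FPKM. MAGEA12, by contrast, was at 49.5 FPKM in control input and listed at 0 in knockdown-labelled input, and CSAG1 was at 156 and 0.73 FPKM. MAGEA3 (98.7 and 110 FPKM), MAGEA6 (77.4 and 93.9 FPKM) and MAGEA4 (284 and 208 FPKM) were expressed in both.

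Medians of the input change with GC content and length removed also differed among the 23 chromosomes compared, a comparison chosen after the data were seen. They were highest on chromosome 8 (0.35 over 247 genes) and chromosome 4 (0.28 over 166 genes), and lowest on chromosome X (-0.30 over 213 genes) and chromosome 7 (-0.29 over 333 genes). Medians of the polyribosome change, also with GC content and length removed, were highest on chromosomes 1 (0.28) and 9 (0.21), and lowest on chromosomes X (-0.49) and 11 (-0.33). These values are relative to the mean of all genes, which was -0.33 before the removal, so a value above 0 is not a rise over control. For the efficiency change, the correlation with chromosomal neighbours was 0.040, within the -0.063 to 0.052 of shuffled gene orders. It was 0.073 for the efficiency of knockdown-labelled cells, above the -0.048 to 0.051 of its shuffled orders, and 0.245 for the polyribosome change.

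A hypothesis tested here, with the test written before its result was seen, was that mRNAs with the CTCCA motif reported for NSUN6 in their 3' UTR have a lower efficiency in knockdown-labelled cells. The 4720 genes with the motif had a median efficiency change of -0.069 and the 2545 genes without it one of -0.23. Shuffling the motif among genes of like 3' UTR length and expression gave medians of -0.30 to -0.24 (between the percentile limits used for lists). Adding GC content to the matching, which the written test did not include, gave -0.11 to -0.08. The genes with the motif lay above both ranges, at the 100th and 99.8th percentiles, so in the header's column order they were not lower. The test was not run with the fractions exchanged. The motif is short and present in most 3' UTRs, sites were not tested for methylation, and the order of the knockdown-labelled columns is open, so this speaks only about the motif's presence in these libraries.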
